A study of Mus musculus with 16 samples.

How the data were processed

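RNA was measured from CD11b-selected brain cells of 16 mice, 4 in each of 4 groups. Per the labels, cells were released from whole brain by enzymatic dissociation and taken with magnetic beads against CD11b, a surface protein of myeloid cells, and libraries were made with a stranded mRNA kit. The labels also hold a growth protocol for cultured cortical neurons; the extraction protocol was taken as the source of the RNA, and the labels do not settle this. The groups combine genotype and treatment. Ntg animals are non-transgenic, and a-syn-tg animals carry human alpha-synuclein under the mThy1 promoter (Line 61). The labels give C57/BL6J for Ntg and a mixed B6 and DBA background for a-syn-tg and do not say whether the animals were littermates, so genotype and strain background are not separated. PLX animals received PLX3397, an inhibitor of the kinase CSF1R, for 3 weeks in the diet at 290 mg per kg and by injection at 40 mg per kg, and vehicle animals received the control diet and solvent. The labels give an age without its unit, so ages are used only as an older cohort (5.4 to 5.5) and a younger cohort (3.7 to 3.9).

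The deposited table holds RSEM expected counts, which are estimated numbers of reads per gene with no normalization by the authors. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.4, STAR 2.7.5c, RSEM 1.3.1 and the genome build mm10, without their order, settings or annotation release. Of the values, 90.6% were exactly whole, and all values were rounded before use. The table has 55401 mouse gene identifiers, of which 55141 matched a symbol in the GENCODE mouse annotation, release 21, on the GRCm38 assembly. Coordinates are from that annotation. Human SNCA has no entry of its own in the table.

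Counts were modelled in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM scaling factors and robust dispersion. Genes were kept by filterByExpr with a minimum count of 10, which left 17658 genes. The model had a term for each group, sex and age cohort, leaving 10 residual degrees of freedom, and all 16 libraries were used in each comparison. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold change. Fold changes are on the log2 scale with a standard error (SE) taken from the F statistic, and levels are normalised counts in CPM with the standard deviation between animals (SD). The common dispersion was 0.0658.

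The comparisons below were fixed before the data were examined: PLX against vehicle in each genotype and over both genotypes, a-syn-tg against Ntg under each treatment, and the interaction of PLX with genotype. The difference between genotypes over both treatments was added after the separate differences had been seen. In vehicle animals the older cohort was female and the younger male, and in PLX animals the older cohort was male and the younger female. Sex and treatment therefore coincided within each cohort, and the sex term equals a cohort by treatment interaction. Animal numbers were not shared between groups, so no pairing was used. Single animals are named by the letter m and the number in their label, such as m467.

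Also fixed before the data were examined were 39 lists of genes for microglial states, pathways and the other cell types that a CD11b selection could hold. Each was tested with camera from limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 39 lists of a comparison. A list needed at least 5 tested members. Members past the test were counted over all genes and adjusted over the list alone. Some members stand in more than 1 list. Every vehicle animal had more than 1 CPM of all 20 astrocyte and all 20 oligodendrocyte genes tested, 14 of 20 neuronal genes and 15 of 16 ependyma and choroid plexus genes, so these lists do not tell which cells held the RNA. For each animal the CPM of each list's members were also summed.

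Named genes follow a rule with 3 parts. The first is Snca, Thy1, Csf1r, Csf1, Il34, Kit, Flt3, P2ry12, Tmem119, Cx3cr1, Trem2 and Apoe in every comparison. The second is the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2, a change of at least 1.5 fold and no overlap between the animals of the 2 groups, without predicted genes and pseudogenes. The third is up to 4 called members per list with the smallest p, or 2 members as values where none were called. The few genes named outside this rule are marked where they appear.

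Total counts ranged from 26.2 to 74.6 M (mega-counts) per library. The fit was tested on simulated data with 200 changed genes among 17658. Of genes changed 2-fold it recovered 58.2% for PLX in Ntg, 44.8% for PLX in a-syn-tg, 79.1% for PLX over both genotypes, 62.7% for genotype under vehicle, 43.3% for genotype under PLX and 40.3% for the interaction. At 4-fold these shares were 81.8%, 78.8%, 89.4%, 81.8%, 71.2% and 69.7%. Wrong calls numbered 2 to 10 per comparison. Genes were drawn independently there, with the same dispersion in every group, and few of them changed. The shares therefore describe the simulation and need not hold for the real comparisons.

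Alternatives fixed before the data were examined were DESeq2-style size factors, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a stricter filter (5 CPM in 4 samples), no covariates, each covariate alone, the groups compared alone, the younger cohort alone, and leaving out each animal. Scaling by total counts alone, thinning all libraries to the smallest total, and leaving out animals m488 and m490 together were added afterwards. The counts of called genes were also obtained under other splits of the animals. All comparisons used every deposited column.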

Results

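The data are gene counts from 16 libraries of CD11b-selected brain cells, 1 library per mouse, in 4 groups of 4 animals. The groups were Ntg and a-syn-tg mice, each given vehicle or PLX3397 (PLX). Total counts averaged 35.4 M ± 10.3 (SD, n = 4) in Ntg vehicle, 28.6 M ± 1.76 in Ntg PLX, 50.2 M ± 17.8 in a-syn-tg vehicle and 28.2 M ± 1.48 in a-syn-tg PLX, with single libraries between 26.2 and 74.6 M. Replicates of a group correlated across genes with r between 0.93 and 0.985. On a principal component analysis, the first component held 46% of the variance and separated every PLX library from every vehicle library. The second held 9.49%, and a-syn-tg PLX animal m488 stood apart on it, at its lower end (-85.8). Ntg PLX animal m467 lay at its upper end (52.1). Xist, the RNA that silences the X chromosome, lay between 70 and 270 CPM in the 8 female libraries and between 0.4 and 8.18 CPM in the 8 male libraries, so the sex labels matched.

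The first question was what inhibition of CSF1R, the receptor through which CSF1 and IL-34 keep microglia alive, did to the RNA of the selected cells. Genes of resting microglia fell in both genotypes. Over both genotypes, P2ry12, a purine receptor of microglial processes, fell by 3.38 ± 0.25 (SE) on the log2 scale, a 10.4-fold lower level (adjusted p = 9.1e-08). P2ry12 (chromosome 3, 59216272 to 59262871, GRCm38, ENSMUSG00000036353) averaged 1841 CPM ± 144 (SD, n = 4) in Ntg vehicle, 302 CPM ± 148 in Ntg PLX, 1952 CPM ± 177 in a-syn-tg vehicle and 189 CPM ± 133 in a-syn-tg PLX. Tmem119, a microglial surface protein, fell by 3.04 ± 0.23 (adjusted p = 1.1e-07), and Cx3cr1, the fractalkine receptor, fell by 2.83 ± 0.23 (adjusted p = 1.7e-07).

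The drug's target Csf1r (chromosome 18, 61100598 to 61132149, ENSMUSG00000024621) fell by 2.77 ± 0.25 over both genotypes, 6.81-fold lower under PLX (adjusted p = 4.1e-07). Csf1r averaged 8466 CPM ± 1043 (SD, n = 4) in Ntg vehicle, 1860 CPM ± 992 in Ntg PLX, 9516 CPM ± 1016 in a-syn-tg vehicle and 1651 CPM ± 1287 in a-syn-tg PLX. Of its ligands, Csf1 fell by 0.88 ± 0.14 (adjusted p = 4.7e-05) and Il34 rose by 0.78 ± 0.14 (adjusted p = 0.00015). In the younger cohort alone Csf1 did not pass (-0.36, adjusted p = 0.16). Kit, a related receptor kinase, rose by 0.87 ± 0.15 (adjusted p = 0.00017), and Flt3 did not pass (-0.15 ± 0.26, adjusted p = 0.63). Trem2, a lipid-sensing receptor of microglia, fell by 2.60 ± 0.23 (adjusted p = 3e-07). Apoe, which carries lipids between cells, showed no detectable change (0.03 ± 0.09, adjusted p = 0.79) with TMM factors. With total counts alone its change was 0.27 (adjusted p = 0.015). Markers of other brain cells rose under PLX too, so the levels of Csf1, Il34, Kit and Apoe do not tell which cells changed.

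**Figure D1:**
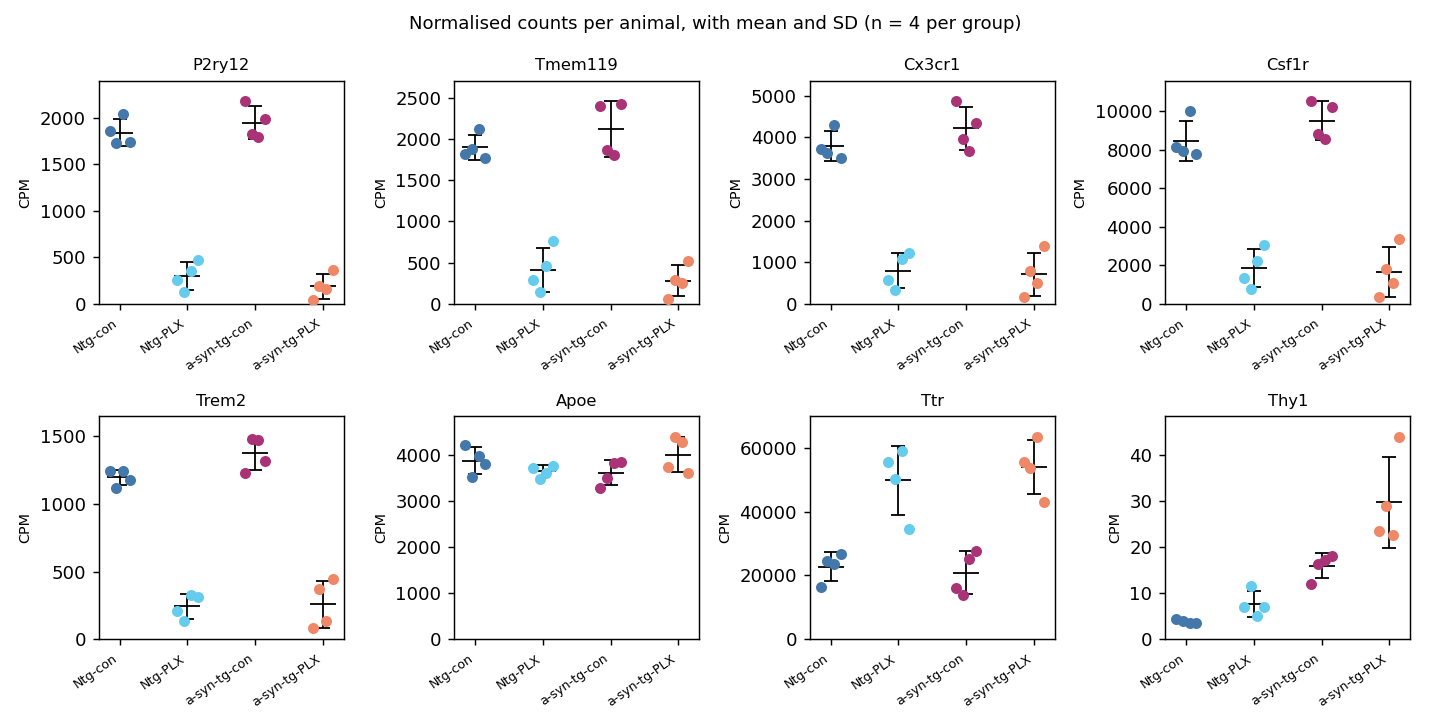
Normalised counts (CPM, vertical axes from 0) of 8 genes in each animal, by group; points are animals, and bars give the mean and SD (n = 4). P2ry12, Tmem119, Cx3cr1, Csf1r and Trem2 lay lower in every PLX animal than in every vehicle animal.

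All 28 tested members of the homeostatic microglia list fell under PLX over both genotypes, with a median of -2.67 on the log2 scale, and all 28 passed when adjusted over the list alone. Besides the genes above, P2ry13 fell by 3.03 ± 0.16, Entpd1, the ectoenzyme CD39, by 1.60 ± 0.09, Ltc4s, which makes leukotriene C4, by 1.61 ± 0.10 and Mef2c, a transcription factor, by 1.56 ± 0.09. Camera placed the list below other genes (adjusted p = 2.5e-26), but not with an estimated correlation (adjusted p = 0.26 with an estimated correlation). The list's summed level averaged 58300 CPM ± 4020 (SD, n = 4) in Ntg vehicle, 14200 CPM ± 5930 in Ntg PLX, 66900 CPM ± 2280 in a-syn-tg vehicle and 12600 CPM ± 7080 in a-syn-tg PLX. Of 35 genes for CSF1R, related kinases, ligands and myeloid regulators, 25 fell and 8 rose, 33 when adjusted over the list alone. Among them Maf fell by 2.32 ± 0.15, Tgfbr1 by 2.69 ± 0.17 and Spi1, which encodes the myeloid factor PU.1, by 2.21 ± 0.15 (list adjusted p = 4.6e-07, and adjusted p = 0.26 with an estimated correlation).

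Genes of the macrophages at the brain's borders also fell. Of 20 tested members, 18 fell and 1 rose, with a median of -2.98, and 19 passed when adjusted over the list alone. Of its members, Cd163, a scavenger receptor for haemoglobin, fell by 3.97 ± 0.30, the mannose receptor Mrc1 by 3.93 ± 0.30, the hyaluronan receptor Lyve1 by 3.81 ± 0.29, Pf4 by 3.72 ± 0.32 and Ms4a7 by 3.55 ± 0.37. Mgl2 fell by 2.86 ± 0.14, Clec4n fell by 3.21 ± 0.17, Cbr2 fell by 2.97 ± 0.15 and Clec10a fell by 2.98 ± 0.17. The list lay below other genes by camera (adjusted p = 4.6e-14) and also with an estimated correlation (adjusted p = 0.027), the only list over both genotypes for which the call held. It held in Ntg (adjusted p = 0.014 with an estimated correlation) and not in a-syn-tg (adjusted p = 0.055 with an estimated correlation). Among the 10 largest falls under the naming rule, those outside this list were Ccl24, a chemokine (-4.39 ± 0.46), Gpr165 of the homeostatic list (-3.94 ± 0.26), Tlr5 of the toll-like receptor list (-3.75 ± 0.25), Bank1 (-3.75 ± 0.21) and Myo18b (-3.70 ± 0.26).

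Of 20 antigen presentation genes, 16 fell and 0 rose, both over all genes and adjusted over the list alone, by edgeR. The class II gene H2-Eb1 fell by 2.55 ± 0.12, H2-Ab1 by 2.39 ± 0.13, H2-Aa by 2.41 ± 0.14 and H2-DMb1 by 1.76 ± 0.10 (list adjusted p = 1.1e-08, and adjusted p = 0.26 with an estimated correlation). Of 32 cytokine and NF-kB target genes, 28 fell and 2 rose, 30 when adjusted over the list alone. Ccl7 fell by 3.28 ± 0.27, Tlr4 by 1.86 ± 0.12, Nfkb1 by 1.26 ± 0.09 and Bcl2a1b by 1.96 ± 0.16 (list adjusted p = 1.5e-11, and adjusted p = 0.26 with an estimated correlation). Of 23 toll-like and Fc receptor genes, 22 fell, as many when adjusted over the list alone, including Tlr1 (-1.92 ± 0.12) and Ticam1 (-1.34 ± 0.10). That list had an adjusted p of 5.7e-13, and adjusted p = 0.26 with an estimated correlation. Since homeostatic microglial genes fell and markers of other brain cells rose too, a change within cells is not separated from a change in which cells were present.

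Of 30 immediate early and dissociation stress genes, 27 fell, as many when adjusted over the list alone: Dusp6 by 1.59 ± 0.10, Ier5 by 2.00 ± 0.17, Rhob by 1.71 ± 0.15 and Atf3 by 1.96 ± 0.18 (list adjusted p = 1.6e-08, and adjusted p = 0.32 with an estimated correlation). Of 25 PI3K and MAPK feedback genes, 16 fell and 4 rose, 21 when adjusted over the list alone, with Myc at -2.32 ± 0.16, Etv5 (-1.92 ± 0.14) and Txnip (-2.07 ± 0.16). That list had an adjusted p of 0.0026, and adjusted p = 0.29 with an estimated correlation. Of 25 p53 and apoptosis genes, 13 fell and 7 rose, 20 when adjusted over the list alone: Casp8 fell by 1.29 ± 0.08, Bbc3 by 1.88 ± 0.15, Casp3 by 1.32 ± 0.11 and Casp1 by 1.93 ± 0.16. The list had an adjusted p of 0.023, and adjusted p = 0.36 with an estimated correlation. Homeostatic microglial genes fell and astrocyte genes rose alongside, so the levels of these 3 lists do not tell which cells changed.

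Genes of the disease-associated state of microglia went both ways: 18 of 30 fell and 8 rose, 26 when adjusted over the list alone. Their summed level averaged 26500 CPM ± 1630 (SD, n = 4) in Ntg vehicle and 13000 CPM ± 2140 in Ntg PLX. In a-syn-tg it averaged 29000 CPM ± 160 under vehicle and 15300 CPM ± 3790 under PLX. Cd68 fell by 2.09 ± 0.16, Cd9 by 1.04 ± 0.08, Tyrobp by 2.15 ± 0.16 and Ctsd by 1.56 ± 0.13. Gpnmb rose by 1.75 ± 0.27, Apoc1 by 1.25 ± 0.18 and Ch25h by 1.73 ± 0.26, which are genes chosen after their values were seen. Gpnmb averaged 5.34 CPM ± 1.78 (SD, n = 4) in Ntg vehicle, 18.2 CPM ± 12.3 in Ntg PLX, 6.57 CPM ± 2.27 in a-syn-tg vehicle and 21.4 CPM ± 4.76 in a-syn-tg PLX. The list lay below other genes (adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation), and without covariates its adjusted p was 0.059. Of 19 complement genes, 13 fell and 5 rose, 18 when adjusted over the list alone. C1qa fell by 2.32 ± 0.20, C5ar2 by 2.81 ± 0.25 and C2 by 2.03 ± 0.18, and the inhibitor Serping1 rose by 1.03 ± 0.09 (list adjusted p = 0.0023, and adjusted p = 0.37 with an estimated correlation). Homeostatic microglial genes fell and markers of other brain cells rose alongside, so neither list tells which cells changed.

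Of 33 interferon response genes, 13 rose and 9 fell, 22 when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.71). Its median was 0.05 and its mean -0.04. Ifit1, an interferon-induced RNA-binding protein, rose by 0.87 ± 0.13, while Trim30a fell by 0.82 ± 0.09, Parp14 by 0.69 ± 0.08 and Ifi207 by 2.45 ± 0.32. Ifitm1, outside that list, rose by 2.04 ± 0.20 and was among the 10 largest rises under the naming rule.

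In the selected material, lysosomal genes fell and cholesterol synthesis genes rose. Astrocyte genes rose alongside (median 1.19), so these levels do not tell which cells changed. Of 46 lysosomal genes, 41 fell and 3 rose, 44 when adjusted over the list alone: Cln3 fell by 1.32 ± 0.08 and Tfe3 by 1.63 ± 0.10 (list adjusted p = 1.4e-14, and adjusted p = 0.26 with an estimated correlation). Of 25 cholesterol synthesis and uptake genes, 21 rose and 1 fell, 22 when adjusted over the list alone. Ldlr, the LDL receptor, rose by 1.17 ± 0.07, Dhcr24 by 1.46 ± 0.09, Hmgcs1 by 0.90 ± 0.07 and Fdft1 by 0.94 ± 0.08 (list adjusted p = 5.6e-08, and adjusted p = 0.26 with an estimated correlation). Of 27 lipid handling and efflux genes, 11 rose and 10 fell, 21 when adjusted over the list alone. Scd1, a fatty acid desaturase, rose by 1.62 ± 0.15, while Cd36 fell by 2.41 ± 0.22, Mylip by 2.27 ± 0.20 and Lpcat3 by 1.06 ± 0.07. That list did not pass (adjusted p = 0.94, median 0.05, mean -0.08), and its camera direction turned to higher with total counts alone (median 0.30).

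Transcripts of the respiratory chain rose and those of ribosomal proteins fell in the selected material, where ependyma and choroid plexus genes rose too (median 1.26), so a change in which cells were present is not separated from a change within cells. All 13 mitochondrially encoded genes rose, with a median of 1.08, and all passed adjusted over the list alone: mt-Nd6 by 1.12 ± 0.10, mt-Atp8 by 1.21 ± 0.11, mt-Atp6 by 1.08 ± 0.10 and mt-Nd2 by 1.13 ± 0.11 (list adjusted p = 1.4e-08, and adjusted p = 0.26 with an estimated correlation). Of 55 nuclear genes for oxidative phosphorylation, 45 rose and 1 fell, 46 when adjusted over the list alone, with a median of 0.44: Atp5g3 rose by 0.70 ± 0.07, Ndufa1 by 0.81 ± 0.08, Cox6c by 0.77 ± 0.09 and Atp5j by 0.61 ± 0.07 (list adjusted p = 4.4e-08, and adjusted p = 0.42 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 76 fell, as many when adjusted over the list alone, with a median of -0.72: Rpl10 by 1.05 ± 0.10, Rplp1 by 1.17 ± 0.12, Rps4x by 1.04 ± 0.11 and Rps29 by 1.01 ± 0.11 (list adjusted p = 3.8e-12, and adjusted p = 0.46 with an estimated correlation). The mitochondrial share of counts was 1.72% ± 0.237 (SD, n = 4) in Ntg vehicle, 4.01% ± 1.06 in Ntg PLX, 1.59% ± 0.127 in a-syn-tg vehicle and 3.49% ± 0.7 in a-syn-tg PLX. Mitochondrially encoded genes were also listed as a sign of RNA quality, and a difference in that quality is not separated either.

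Of 24 glycolysis and hypoxia genes, 16 rose and 4 fell, 20 when adjusted over the list alone: Pfkp rose by 1.24 ± 0.10, Hk1 by 0.72 ± 0.07 and Pgk1 by 0.75 ± 0.07, and Pdk1 fell by 0.80 ± 0.07. The list had an adjusted p of 0.014, and adjusted p = 0.26 with an estimated correlation. Without a-syn-tg PLX animal m489 it did not pass (adjusted p = 0.071). Astrocyte and endothelial genes rose alongside, so it does not tell which cells changed. Of 39 matrix genes, 13 of them also in other lists, 22 rose and 8 fell, 30 when adjusted over the list alone: Sparcl1 rose by 1.31 ± 0.13 and Timp3 by 0.94 ± 0.10, and Sparc fell by 1.36 ± 0.13 and Adam17 by 0.92 ± 0.09 (list adjusted p = 0.023, and adjusted p = 0.26 with an estimated correlation). Genes of fibroblasts and meninges (median 1.07) and of pericytes and smooth muscle (median 0.94) rose as well, so the list does not tell which cells changed. Of 25 genes of the unfolded protein and integrated stress responses, 15 fell and 4 rose, 19 when adjusted over the list alone. Herpud1 fell by 1.20 ± 0.12, Atf4 by 0.77 ± 0.08 and Ddit3 by 0.96 ± 0.11, and Vldlr rose by 1.39 ± 0.15; the list did not pass (adjusted p = 0.087). Without Ntg PLX animal m490 that list's adjusted p was 0.038. Of 23 antioxidant and iron genes, 10 rose and 9 fell, 19 when adjusted over the list alone. Hmox1 fell by 2.64 ± 0.24, Slc11a1 by 2.17 ± 0.17, Ftl1 by 1.55 ± 0.13 and Gclc by 0.73 ± 0.07, and the list did not pass (adjusted p = 0.49).

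Of 21 synuclein and parkinsonism genes, 9 fell and 8 rose, 18 when adjusted over the list alone, and the list did not pass (adjusted p = 0.98, median -0.09, mean 0.14). Lrrk2, a kinase mutated in familial parkinsonism, rose by 1.09 ± 0.09, and Gba, the lysosomal glucocerebrosidase, fell by 0.98 ± 0.08, Scarb2 by 0.93 ± 0.08 and Synj1 by 0.64 ± 0.07. Mouse Snca (chromosome 6, 60731575 to 60829855, ENSMUSG00000025889) fell by 0.87 ± 0.31 (adjusted p = 0.022). Snca averaged 6.73 CPM ± 1.47 (SD, n = 4) in Ntg vehicle, 4.18 CPM ± 1.84 in Ntg PLX, 9.09 CPM ± 3.42 in a-syn-tg vehicle and 3.75 CPM ± 1.93 in a-syn-tg PLX. Summed erythroid genes averaged 6090 CPM ± 1050 (SD, n = 4) in Ntg vehicle and 3430 CPM ± 1440 in Ntg PLX. In a-syn-tg they averaged 8680 CPM ± 3900 under vehicle and 2740 CPM ± 1410 under PLX. Snca and this sum were both lowest in m488 (0.863 and 1037 CPM) and m490 (1.88 and 1322 CPM). Both were highest in m483 (12.4 and 12240 CPM) and m484 (11.2 and 11560 CPM). Ranks differed among the other animals. The fall of Snca is not separated from the amount of red cell RNA. The Snca call was lost without Ntg PLX animal m467 (adjusted p = 0.052), a-syn-tg PLX animal m468 (0.067) or a-syn-tg vehicle animal m477 (0.061), without the filter (0.063) and with total counts alone (0.076).

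Markers of other brain cells were higher under PLX. Ttr, the transthyretin made by the choroid plexus and chosen after its values were seen, took 2.14% ± 0.437 of counts (SD, n = 4) in Ntg vehicle, 5.42% ± 1.13 in Ntg PLX, 1.88% ± 0.609 in a-syn-tg vehicle and 5.86% ± 1.02 in a-syn-tg PLX. All 16 ependyma and choroid plexus genes rose (median 1.26), among them Otx2 by 1.29 ± 0.14, Clic6 by 1.37 ± 0.16, Sostdc1 by 1.25 ± 0.15 and Kl by 1.34 ± 0.17 (list adjusted p = 1.5e-06, and adjusted p = 0.32 with an estimated correlation). All 20 astrocyte genes rose (median 1.19), among them Aldh1l1 by 1.44 ± 0.14, Atp1a2 by 1.03 ± 0.11, Mt3 by 1.22 ± 0.14 and Slco1c1 by 0.96 ± 0.13 (list adjusted p = 1.7e-05, and adjusted p = 0.42 with an estimated correlation). Gfap, the astrocyte filament protein, rose by 2.02 ± 0.29, one of the 10 largest rises under the naming rule. All 15 genes of fibroblasts and meninges rose (median 1.07), among them Pdgfra by 1.31 ± 0.10, Ogn by 1.18 ± 0.12, Fbln1 by 1.13 ± 0.12 and Col1a2 by 1.09 ± 0.13 (list adjusted p = 1.4e-05, and adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, every member of these lists passed: 16, 20 and 15.

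All 15 genes of pericytes and smooth muscle rose (median 0.94), 15 when adjusted over the list alone, among them Acta2 by 1.19 ± 0.14, Myl9 by 1.23 ± 0.14, Myh11 by 1.13 ± 0.14 and Cspg4 by 0.94 ± 0.11 (list adjusted p = 1.7e-05, and adjusted p = 0.37 with an estimated correlation). Of 20 endothelial genes, 19 rose, 19 when adjusted over the list alone (median 0.88), among them Vwf by 1.52 ± 0.15, Cdh5 by 0.89 ± 0.12, Ly6a by 1.04 ± 0.14 and Slc2a1 by 0.86 ± 0.12 (list adjusted p = 3.9e-06, and adjusted p = 0.42 with an estimated correlation). Of 20 neuronal genes, 15 rose, 15 when adjusted over the list alone (median 0.93), among them Map2 by 1.25 ± 0.15, Stmn2 by 1.22 ± 0.17, Celf4 by 0.93 ± 0.20 and Thy1 by 0.99 ± 0.19 (list adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation). Of 15 genes of oligodendrocyte precursors, 7 rose, 6 when adjusted over the list alone (median 0.92), with Bmp4 up by 0.93 ± 0.13 and the PDGF receptor Pdgfra by 1.31 ± 0.10 (list adjusted p = 0.03, and adjusted p = 0.51 with an estimated correlation). With total counts alone the neuron list (adjusted p = 0.063) and the precursor list (adjusted p = 0.11) did not pass.

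Oligodendrocyte genes moved unequally: 7 of 20 rose and 2 fell, 7 when adjusted over the list alone, and the list did not pass (adjusted p = 0.49, median -0.10, mean 0.20). Mbp, a myelin protein, rose by 2.57 ± 0.49, Enpp2 by 1.27 ± 0.17 and Cryab by 0.82 ± 0.14, and Trf, transferrin, fell by 1.22 ± 0.11. In the younger cohort alone Mbp did not pass (1.79, adjusted p = 0.051). The list's summed level averaged 12400 CPM ± 2450 (SD, n = 4) in Ntg vehicle, 24000 CPM ± 4320 in Ntg PLX, 12100 CPM ± 1950 in a-syn-tg vehicle and 25700 CPM ± 4760 in a-syn-tg PLX. The further rises among the 10 largest under that rule were Cxcr2 (2.16 ± 0.27), Shank1 (2.07 ± 0.30), Unc80 (1.98 ± 0.28), Rapgef4 (1.90 ± 0.24), Ntm (1.84 ± 0.20), Steap4 (1.80 ± 0.22), Trnp1 (1.79 ± 0.22) and Sh3rf2 (1.78 ± 0.26).

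**Figure D2:**
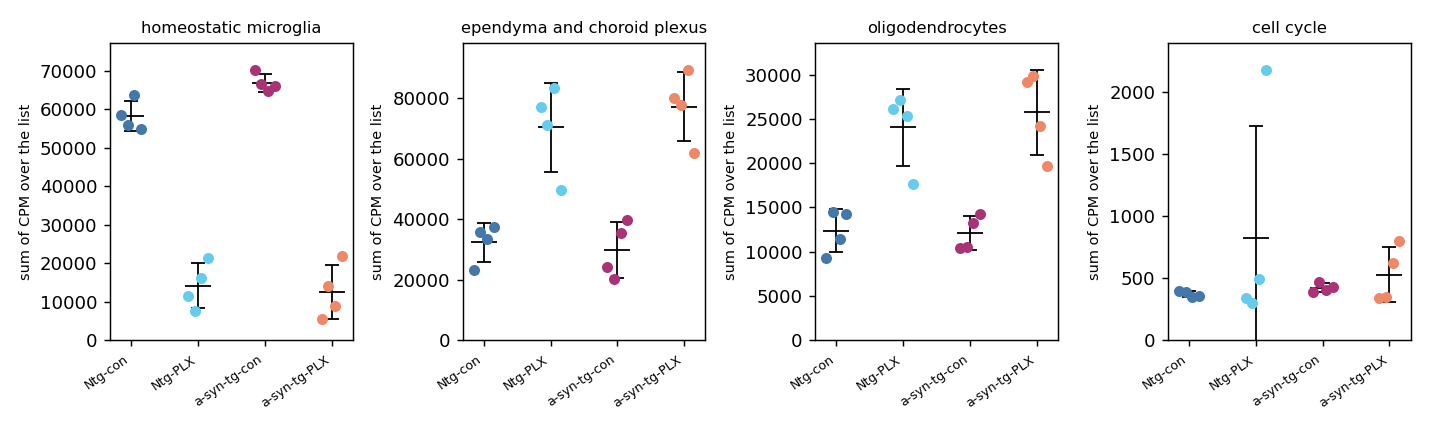
Summed normalised counts (CPM, vertical axes from 0) over the members of 4 gene lists in each animal, by group; points are animals, and bars give the mean and SD (n = 4). The homeostatic sum lay lower and the ependyma and choroid plexus sum higher in every PLX animal than in every vehicle animal, and 1 Ntg PLX animal had a cell cycle sum of 2170 CPM.

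Among blood and lymphoid cells, 12 of 24 neutrophil genes rose and 1 fell, 13 when adjusted over the list alone. Cxcr2, a chemokine receptor, rose by 2.16 ± 0.27, and Hdc by 0.94 ± 0.15, and Csf3r fell by 1.76 ± 0.17 (list adjusted p = 0.045, and adjusted p = 0.63 with an estimated correlation). Summed neutrophil genes averaged 904 CPM ± 196 (SD, n = 4) in Ntg vehicle and 1050 CPM ± 332 in Ntg PLX. In a-syn-tg they averaged 1120 CPM ± 446 under vehicle and 894 CPM ± 240 under PLX, so the sum did not rise there. Of 20 monocyte genes, 9 rose and 2 fell, 11 when adjusted over the list alone. Ace rose by 1.28 ± 0.15, S100a6 by 1.11 ± 0.14 and Fn1 by 0.88 ± 0.12, and Treml4 fell by 2.29 ± 0.34 (list adjusted p = 0.049, and adjusted p = 0.62 with an estimated correlation). Both calls were lost without single animals, among them Ntg PLX animal m467 (neutrophils adjusted p = 0.07, monocytes adjusted p = 0.079) and a-syn-tg PLX animal m468 (0.11 and 0.073), and with total counts alone (0.19 and 0.12). Of 14 dendritic cell genes, 6 fell and 3 rose, 9 when adjusted over the list alone. Fscn1 fell by 2.86 ± 0.20, Wdfy4 by 2.26 ± 0.18, Cd209a fell by 2.42 ± 0.23 and Batf3 by 1.87 ± 0.25 (list adjusted p = 0.15). Of 16 B cell genes, 4 fell and 3 rose, 5 when adjusted over the list alone. Ighd fell by 2.46 ± 0.21, Ighm by 2.78 ± 0.24 and Cd79b by 1.91 ± 0.27, and Ebf1 rose by 1.13 ± 0.15 (list adjusted p = 0.73, median 0.42, mean -0.08). Of 26 T and NK cell genes, 8 rose and 2 fell, 5 when adjusted over the list alone. Klrb1c rose by 0.66 ± 0.13 and Gzmb by 0.76 ± 0.20, and Cd4 fell by 2.33 ± 0.29 (list adjusted p = 0.3). Of 9 erythroid genes, 7 fell, 7 when adjusted over the list alone; Hba-a1 fell by 1.12 ± 0.30, Hbb-bs by 1.22 ± 0.33, and Alas2 by 1.12 ± 0.34 (list adjusted p = 0.32).

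Cell cycle genes depended on the animal. Of 38 genes, 14 rose and 1 fell over both genotypes, but 0 passed when adjusted over the list alone by edgeR, and the list did not pass (adjusted p = 0.11, median 1.00). Ccne2 rose by 1.64 ± 0.44, Ccne1 by 1.88 ± 0.52 and Stmn1 by 0.69 ± 0.21, and Mcm3 fell by 0.85 ± 0.27. The call of Stmn1, PLX vs vehicle over both genotypes, was lost without a-syn-tg PLX animal m468 (0.50, adjusted p = 0.068) or a-syn-tg vehicle animal m477 (0.57, adjusted p = 0.063). In Ntg, 20 rose with a median of 1.74 (list adjusted p = 0.0029, and adjusted p = 0.66 with an estimated correlation), and in a-syn-tg 0 rose and 1 fell with a median of 0.31 (list adjusted p = 0.73). The summed level was 2170 CPM in Ntg PLX animal m490 and 300 to 495 CPM in the other Ntg PLX animals, against 351 to 399 CPM in Ntg vehicle. Ntg PLX animals m466 (338 CPM) and m467 (300 CPM) lay below all Ntg vehicle animals, so the higher Ntg sum rests mostly on m490. The list passed without Ntg PLX animal m487 (adjusted p = 0.034) and without a-syn-tg PLX animal m481 (adjusted p = 0.02). Of the 5 sex-linked genes, Kdm5d on the Y chromosome had a fitted value of -1.65 ± 0.58 (adjusted p = 0.026). It lay between 17.3 and 21.1 CPM in the males of both treatments and between 0 and 0.06 CPM in females. This value therefore does not show a fall. The call was lost without a-syn-tg vehicle animal m477 (-0.01, adjusted p = 1), the only female with counts, or a-syn-tg PLX animal m468 (adjusted p = 0.057). Of these genes 0 passed adjusted over the list alone, and the list did not pass (adjusted p = 0.99).

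Over both genotypes, edgeR called 11619 of 17658 genes, 5842 higher and 5777 lower, of which 2752 and 1948 changed at least 2-fold. In 5430 of them (46.7%) the animals of the treatments did not overlap. Chance gives 0.016% for a gene taken at random, but called genes are already selected for separation, so these shares cannot be compared. With total counts alone (PLX vs vehicle over both genotypes), the median of all genes moved from 0.04 to 0.28 and the share of called genes that were higher from 50.3% to 67.1%, so directions are relative to the TMM scale. By camera, 27 of 39 lists passed, and 1 with an estimated correlation. Within each age cohort sex and treatment coincided, so the drug effect rests on an additive sex term, and cell numbers were not measured.

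**Figure D3:**
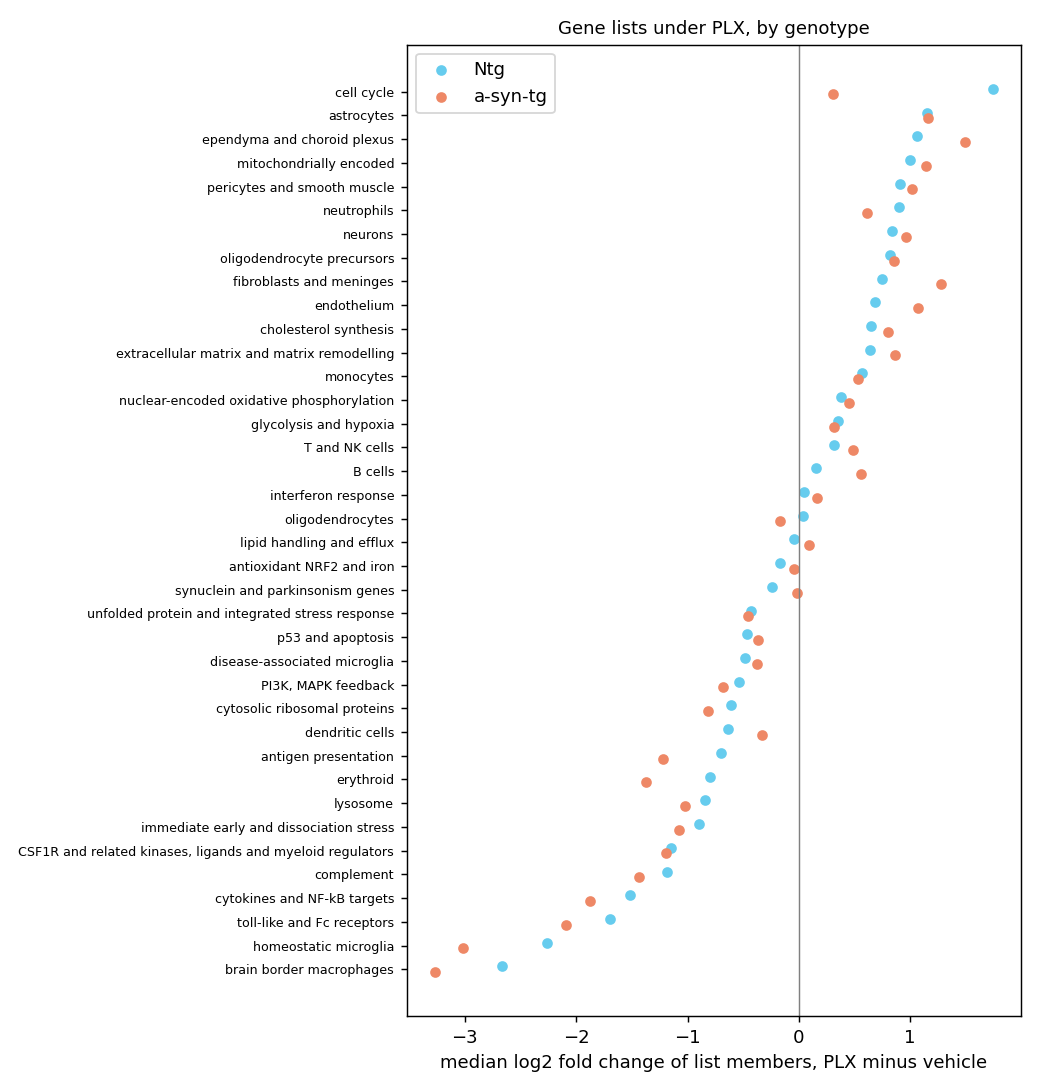
Median log2 fold change of the tested members of each gene list (horizontal axis), PLX minus vehicle, in Ntg and a-syn-tg; each point is 1 list in 1 genotype. Brain border macrophage and homeostatic microglia lists had the lowest medians in both genotypes.

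Within Ntg mice, edgeR called 8818 genes, 4220 higher and 4598 lower, and within a-syn-tg mice 9757 genes, 4754 higher and 5003 lower. The 2-fold counts were 1657 higher and 1561 lower in Ntg and 2798 higher and 1995 lower in a-syn-tg. The animals did not overlap for 7283 of the Ntg calls (82.6%) and 7968 of the a-syn-tg calls (81.7%). Chance gives 2.9% for a gene taken at random, which is no measure for genes already called. In the younger cohort alone, with m482 and m485 under vehicle and m487 and m490 under PLX, the Ntg count was 2826. The smaller count cannot be told apart from the loss of animals. The share of calls that were higher was 47.9% in Ntg and 48.7% in a-syn-tg, and with total counts alone 66.3% and 67.8% (PLX vs vehicle in Ntg and PLX vs vehicle in a-syn-tg). In Ntg P2ry12 fell by 2.69 ± 0.33, Tmem119 by 2.38 ± 0.31, Cx3cr1 by 2.39 ± 0.30, Csf1r by 2.31 ± 0.33 and Trem2 by 2.34 ± 0.30, and Csf1r had an adjusted p of 8.3e-05. In a-syn-tg P2ry12 fell by 4.06 ± 0.37, Tmem119 by 3.69 ± 0.34, Cx3cr1 by 3.27 ± 0.34, Csf1r by 3.22 ± 0.37 and Trem2 by 2.86 ± 0.33. In the younger cohort alone, where sex and treatment coincide, the a-syn-tg values (P2ry12, PLX vs vehicle in a-syn-tg, and Csf1r, PLX vs vehicle in a-syn-tg) were -2.98 (adjusted p = 0.00052) and -2.15 (adjusted p = 0.0028).

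Among called genes with a mean log2 CPM of at least 2 and no overlap between the animals, the largest falls in Ntg were those of Ccl24 (-3.81 ± 0.60), Cd163 (-3.54 ± 0.39), Cd209f (-3.39 ± 0.43), Gpr165 (-3.36 ± 0.33), Mrc1 (-3.25 ± 0.38), Cd300ld3 (-3.19 ± 0.47), Myo18b (-3.10 ± 0.34), Tlr5 (-3.09 ± 0.33), Ms4a7 (-3.02 ± 0.49) and Ccl7 (-2.97 ± 0.36). In a-syn-tg they were those of Bank1 (-4.71 ± 0.30), Mrc1 (-4.62 ± 0.43), Pf4 (-4.54 ± 0.48), Gpr165 (-4.51 ± 0.37), Tlr5 (-4.41 ± 0.36), Cd163 (-4.41 ± 0.43), Slc2a5 (-4.38 ± 0.44), Myo18b (-4.30 ± 0.37), Gp9 (-4.17 ± 0.21) and Crybb1 (-4.15 ± 0.37). The largest rises in Ntg among such genes included neuronal and myelin genes: Rgs8 (2.94 ± 0.74), Pcdhgc4 (2.91 ± 0.72), Gng13 (2.77 ± 0.48), Kif5a (2.39 ± 0.71), Bcas1 (2.37 ± 0.70), Mobp (2.35 ± 0.72), Mbp (2.34 ± 0.66), S100a5 (2.30 ± 0.65), Rph3a (2.28 ± 0.63) and Omp (2.26 ± 0.63), the olfactory marker protein. In the younger cohort alone, which has fewer animals, of these Rgs8, Gng13, Kif5a, Bcas1, Mobp, Mbp, S100a5, Rph3a and Omp did not pass. In a-syn-tg the largest rise among such genes was that of Lrg1 (3.59 ± 0.80), a secreted glycoprotein of inflamed vessels and neutrophils, followed by Gng13 (3.24 ± 0.54), S100a5 (2.96 ± 0.75), Omp (2.96 ± 0.73), Unc13c (2.92 ± 0.52), Stoml3 (2.56 ± 0.56), Serpina3n (2.46 ± 0.59), Cxcr2 (2.35 ± 0.38), Ifitm1 (2.27 ± 0.29) and Asprv1 (2.11 ± 0.53).

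The PLX effects of the genotypes were alike in direction. Across 17658 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.814 and rho = 0.871, with a covariance of 0.98. In 20 simulated draws of unchanged groups r averaged 0.03, between -0.001 and 0.07. Each gene was drawn independently there, while genes of real animals vary together. The draws therefore do not show how far r would vary without a drug effect. Of the called genes, 7862 were called in both genotypes with the same direction, 3686 higher and 4176 lower, and 0 by edgeR with opposite directions; independent lists would give 1136 and 1303. Among them the a-syn-tg change was 1.22 times the Ntg change at the median. Whether a gene's effect differed between the genotypes is tested by the interaction.

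**Figure D4:**
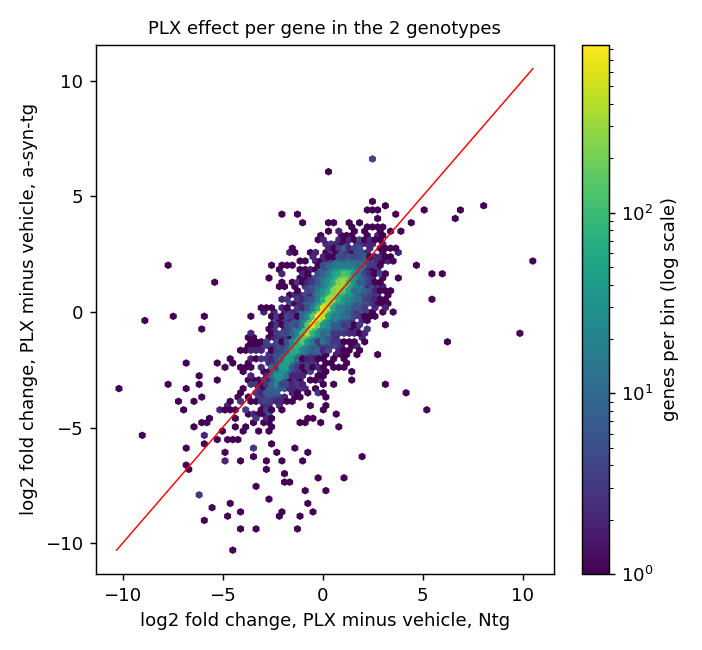
Log2 fold change per gene, PLX minus vehicle, in Ntg (horizontal axis) and a-syn-tg (vertical axis); colour gives the number of genes per bin on a log scale, and the red line marks equal effects. The changes correlated with r = 0.814, which does not measure closeness to the line. Among genes called in both genotypes the a-syn-tg change was 1.22 times the Ntg change at the median.

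The second question was whether the selected cells of a-syn-tg mice differed from those of Ntg mice, whose strain background differs by the labels. Under vehicle, the 12 genes chosen in advance differed little apart from Thy1 (chromosome 9, 44043384 to 44048579, ENSMUSG00000032011), whose promoter drives the transgene. Whether transgene reads were counted as Thy1 cannot be told from these counts, which hold no entry for human SNCA. Thy1 averaged 3.81 CPM ± 0.424 (SD, n = 4) in Ntg vehicle, 7.63 CPM ± 2.81 in Ntg PLX, 15.9 CPM ± 2.7 in a-syn-tg vehicle and 29.7 CPM ± 9.88 in a-syn-tg PLX. The Thy1 difference was 2.03 ± 0.28 under each treatment and did not pass (adjusted p = 0.081 each). Over both treatments, a comparison added after these values were seen, it was 2.03 ± 0.20 and passed (adjusted p = 0.0013), with every a-syn-tg animal above every Ntg animal of its treatment. Under vehicle P2ry12 (0.10 ± 0.31, adjusted p = 1), Csf1r (0.17 ± 0.32, adjusted p = 1), Trem2 (0.17 ± 0.30, adjusted p = 1), Apoe (-0.13 ± 0.13, adjusted p = 1) and mouse Snca (0.35 ± 0.43, adjusted p = 1) did not pass.

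Under vehicle, edgeR called 0 genes, with 565 at an unadjusted p under 0.05 where 883 are expected by chance; DESeq2 called 10 and limma-voom 1. Under PLX, edgeR called 0 genes, with 861 at an unadjusted p under 0.05; DESeq2 called 35 and limma-voom 0. Without a-syn-tg PLX animal m489, edgeR called 84 genes under PLX, among them P2ry12 (-1.62, adjusted p = 0.028) and Tmem119 (-1.42, adjusted p = 0.036). It called 6 without Ntg PLX animal m487, 2 without a-syn-tg PLX animal m488 and 1 without Ntg PLX animal m467. The comparison of Thy1, a-syn-tg vs Ntg under vehicle, passed without Ntg PLX animal m467 (adjusted p = 0.021), a-syn-tg PLX animal m468 (0.031) or a-syn-tg PLX animal m489 (0.0082), without covariates (0.0096), with sex alone (0.032), with age cohort alone (0.026), with the compared groups alone (0.0098), by limma-voom (0.0054) and by DESeq2 (3.1e-09).

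Under vehicle, camera placed 17 of 39 lists apart, 9 higher and 8 lower in a-syn-tg, and 0 with an estimated correlation, where the smallest adjusted p was 0.78. The homeostatic list had a median of 0.17, with Ltc4s at 0.20 ± 0.13 and Sparc at 0.26 ± 0.18, the ribosomal protein list 0.18 and the lysosome list 0.14. The ependyma and choroid plexus list had a median of -0.40, with 3 members lower when adjusted over the list alone and Tmem212 at -1.79 ± 0.58; the astrocyte list had a median of -0.27, with Atp1a2 at -0.40 ± 0.16. In the cholesterol synthesis list (median -0.19), Ldlr at -0.42 ± 0.10 passed when adjusted over the list alone, as the only member.

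Under PLX, no gene of the homeostatic list passed between the genotypes over all genes by edgeR. The summed level of the list overlapped between them, at 14200 CPM ± 5930 (SD, n = 4) in Ntg and 12600 CPM ± 7080 in a-syn-tg, where animal m489 had the highest sum of all PLX animals (21820 CPM). The fitted differences had a median of -0.66, and 9 of 28 members passed when adjusted over the list alone (list adjusted p = 1.3e-23, and adjusted p = 0.56 with an estimated correlation). P2ry12 differed by -1.28 ± 0.34 (adjusted p = 0.79), P2ry13 differed by -1.04 ± 0.21 (adjusted p = 0.39) and Tmem119 differed by -1.14 ± 0.32 (adjusted p = 0.79). By DESeq2 P2ry12 had -1.29 (adjusted p = 0.014) and Tmem119 -1.14 (adjusted p = 0.036). The brain border macrophage list had a median of -0.59, and 7 of 20 members passed when adjusted over the list alone (list adjusted p = 6.3e-11, and adjusted p = 0.081 with an estimated correlation). Cbr2 differed by -1.43 ± 0.22 (adjusted p = 0.094) and Lyve1 differed by -2.23 ± 0.41 (adjusted p = 0.24). Spp1, osteopontin, differed by 1.23 ± 0.25 (adjusted p = 0.39) and Mmp12, a macrophage elastase, differed by 1.61 ± 0.48 (adjusted p = 0.79). Camera placed 13 of 39 lists apart, 4 higher and 9 lower, and 0 with an estimated correlation.

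The third question was whether PLX acted differently in the genotypes. The interaction, which is the a-syn-tg effect minus the Ntg effect, did not pass for P2ry12 (-1.38 ± 0.47, adjusted p = 0.95), Tmem119 (-1.31 ± 0.44, adjusted p = 0.95), Csf1r (-0.91 ± 0.47, adjusted p = 0.95), Spp1 (1.14 ± 0.35, adjusted p = 0.95), Cbr2 (-1.52 ± 0.29, adjusted p = 0.65) or Thy1 (0.00 ± 0.44, adjusted p = 1). By edgeR 0 genes were called, with 738 at an unadjusted p under 0.05 where 883 are expected; DESeq2 called 16 and limma-voom 0. Without Ntg PLX animal m487, edgeR called 4. The homeostatic list had a median of -0.85, the cell cycle list -1.22 and the ependyma and choroid plexus list 0.48. Camera placed 16 of 39 lists apart, 5 higher and 11 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.22.

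A last planned question, whether PLX moved genes that differ between the genotypes back towards the Ntg vehicle level, could not be asked, since edgeR called 0 genes between the genotypes under vehicle, with 565 at an unadjusted p under 0.05, against 10 by DESeq2 and 1 by limma-voom.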

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

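The splits of the animals were planned, the thinning was added after the first results, and the tests of gaps between lists, over all animals and within each genotype, of all pairs of lists and of cell cycle sums across animals were chosen only after the result was seen. In the search for single animals far from their group, 8 of 204 groups held one, where about 10 are expected by chance. Antigen presentation genes summed to 6130 CPM in a-syn-tg vehicle animal m483, and to between 6340 and 6380 CPM in the other animals of its group. Cell cycle genes summed to 2170 CPM in Ntg PLX animal m490 (others 300 to 495). Dendritic cell genes summed to 976 CPM in Ntg vehicle animal m482 (others 870 to 882). Endothelial genes summed to 6800 CPM in Ntg vehicle animal m474 (others 5340 to 5550). Genes of fibroblasts and meninges summed to 2730 CPM in Ntg PLX animal m490 (others 3710 to 3870). Snca stood at 0.863 CPM in a-syn-tg PLX animal m488 (others 4.53 to 4.92), Csf1r at 10000 CPM in Ntg vehicle animal m482 (others 7790 to 8140) and Kit at 4.28 CPM in a-syn-tg vehicle animal m484 (others 3.55 to 3.68). Animal m488 also had the lowest erythroid sum of its group, 1037 CPM, where the others had 2576 to 4481 CPM.

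For the number of genes called for PLX in Ntg, 8818, chance is unlikely. There 1 of 35 splits, the real one, gave as many and the highest other gave 1. This is the smallest share that 35 splits allow, and it concerns the number of calls and not single genes. Chance is also unlikely for the number called in a-syn-tg, 9757, where 1 of 35 splits gave as many and the highest other gave 0. It is unlikely too for the 11619 calls over both genotypes, where 1 of 100 splits gave as many and the highest other gave 9382. That highest value points to a structure of the samples, since free relabelling can leave most animals of a treatment together. For the genotype under vehicle edgeR called 0 genes, and any split gives at least as many (35 of 35, highest other 2), so that test is void and says nothing about chance; 565 genes had an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 1. The same holds for the genotype under PLX (0 genes by edgeR, 35 of 35 splits, with 861 genes at an unadjusted p under 0.05, 35 called by DESeq2 and 0 by limma-voom), where the highest other split, 447, points to a structure among PLX animals. It holds as well for the interaction (0 genes by edgeR, 100 of 100 splits, highest other 8941 where splits mix the treatments, with 738 genes at an unadjusted p under 0.05, 16 called by DESeq2 and 0 by limma-voom). For the genotype over both treatments, with 1 gene called, 10 of 100 splits gave as many and the highest other gave 40, so chance cannot be excluded for that count.

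Markers of neurons, astrocytes, vessels and choroid plexus were higher under PLX. A candidate explanation is a lower share of microglia among the selected cells. The gap between the ependyma and choroid plexus list and the neutrophil list changed by 0.72 on the log2 scale with an exact p of 0.11, which does not settle it. The gap changed for 7 of 28 pairs of brain cell lists, 2 of them without oligodendrocytes, with a smallest adjusted exact p of 0.0057. The lists therefore did not rise equally. They do not tell which cells held the RNA, so the pairs cannot decide whether other brain cells rose equally. The mean of the oligodendrocyte list rose by 0.12 (exact p = 0.71), while its sum went from 12400 to 24000 CPM in Ntg. Smaller libraries were argued against by a median of 0.95 over the 8 lists (SD 0.42) after thinning. A lower share of microglia, with equal or unequal change of other cells, stays open, since cell numbers were not measured.

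Homeostatic genes fell by unequal amounts under PLX. Against a lower share of microglia as the only source, the gap between the homeostatic list and the C1q genes changed by -0.24 on the log2 scale with an exact p of 0.009 over 4900 permutations. That gap averaged -2.23 ± 0.02 (SD, n = 4) in Ntg vehicle, -2.33 ± 0.13 in Ntg PLX, -2.33 ± 0.15 in a-syn-tg vehicle and -2.72 ± 0.25 in a-syn-tg PLX. Within a-syn-tg it changed by -0.38 with an exact p of 0.029, the smallest that 70 permutations allow, and within Ntg by -0.10 with an exact p of 0.31, so for Ntg alone a lower share stays open; the genotypes were not tested against each other. Smaller libraries were argued against by a gap of -0.24 after thinning, with an exact p of 0.0086. A change of state in the remaining cells may contribute, as a hypothesis found and tested on the same data, and a change in which myeloid cells remained stays open. Sex and age cohort of the animals were not separated from it.

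Cell cycle genes were high in some PLX animals. One library alone as the source was argued against by 3 of 7 other PLX animals above the highest vehicle animal (469 CPM), although the second highest sum was 797 CPM against 2170 CPM. Younger and older PLX animals differed by 1.13 on the log2 scale with an exact p of 0.071 over 56 splits, and the lowest younger sum, 348 CPM, lay above the highest older sum, 342 CPM. Age cohort and sex may therefore contribute, and the younger PLX animals were all female, so they cannot be told apart. Cells dividing to refill the brain after loss stay an untested explanation.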

How the results depend on the processing

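The alternatives with total counts, thinning and libraries m488 and m490 left out together were chosen only after the result was seen. Sex and treatment coincided within each age cohort, so the younger cohort alone cannot separate them, and 10 residual degrees of freedom limit each test. The younger cohort alone also holds fewer animals, so calls lost there do not show a dependence on cohort. The material was selected cells, and the cause of any difference between settings was not tested. Not run were other pseudocounts and value filters, since the table holds counts, and the compared groups alone for comparisons that use all 16 animals. Under the other settings, 3425 gene values kept their call and direction, 39 reversed sign, 21 gained a call and 36 lost one. Of list values, 415 kept, 19 reversed, 6 gained and 28 lost, and of counts 82 stayed near the first value and 19 moved. With 1 animal left out, 4540 gene values kept, 33 reversed, 11 gained and 8 lost. Of list values 597 kept, 9 reversed, 3 gained and 15 lost, and of counts 118 stayed near the first value and 10 moved.

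With total counts alone, reversed in sign were Apoe 0.12 in Ntg under PLX, Flt3 0.09 under PLX over both genotypes and Kit -0.06 between genotypes under vehicle. Apoe under PLX over both genotypes and Apoe in a-syn-tg under PLX gained calls. Mcm3 and Snca under PLX over both genotypes lost calls. Lists whose call or direction moved had medians over both genotypes of lipid handling and efflux 0.30, monocytes 0.79, neurons 1.18, neutrophils 1.02, oligodendrocyte precursors 1.16, sex-linked -0.24 and synuclein and parkinsonism genes 0.15. By DESeq2, reversed in sign were Apoe 0.00 between genotypes over both treatments and Thy1 -0.01 in the interaction. Snca in a-syn-tg under PLX and Thy1 between genotypes under vehicle and P2ry12, Thy1 and Tmem119 between genotypes under PLX gained calls. Kdm5d under PLX over both genotypes lost a call. Over both genotypes, lists whose call or direction moved had medians of monocytes 0.54, neutrophils 0.78 and sex-linked -0.21. Called genes numbered 7 between genotypes over both treatments, 35 between genotypes under PLX, 10 between genotypes under vehicle and 16 in the interaction.

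With DESeq2-style size factors, reversed in sign were Apoe 0.00 between genotypes over both treatments and Thy1 -0.01 in the interaction. Medians of lists that moved in call or direction were, over both genotypes, monocytes 0.54 and sex-linked -0.37. By limma-voom, reversed in sign were Apoe 0.02 between genotypes over both treatments, Flt3 -0.01 in a-syn-tg under PLX, Flt3 0.17 between genotypes under vehicle, Kit -0.09 between genotypes under vehicle, Snca -0.19 between genotypes under PLX and Thy1 -0.05 in the interaction. Snca in a-syn-tg under PLX and Thy1 between genotypes under vehicle gained calls. Kdm5d under PLX over both genotypes lost a call. Lists whose call or direction moved had medians over both genotypes of lipid handling and efflux 0.06, oligodendrocyte precursors 0.59, p53 and apoptosis -0.42 and unfolded protein and integrated stress response -0.47. Called genes numbered 1 between genotypes under vehicle.

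Without covariates, reversed in sign were Apoe 0.02 between genotypes over both treatments, Csf1 0.11 in the interaction, Il34 -0.04 between genotypes under PLX, Kit -0.02 between genotypes under vehicle, Snca -0.16 between genotypes under PLX, Thy1 -0.10 in the interaction, Trem2 0.14 between genotypes over both treatments and Trem2 0.08 between genotypes under PLX. Snca in a-syn-tg under PLX and Thy1 between genotypes under vehicle and Thy1 between genotypes under PLX gained calls. Kdm5d and Mcm3 under PLX over both genotypes lost calls. Over both genotypes, lists whose call or direction moved had medians of disease-associated microglia -0.35, monocytes 0.39, neutrophils 0.60 and sex-linked -0.83. Called genes numbered 2 between genotypes over both treatments, 3 between genotypes under PLX and 1 between genotypes under vehicle. The agreement of the PLX effect between genotypes, a correlation across genes that are not independent, was 0.784. With sex alone, reversed in sign were Apoe 0.02 between genotypes over both treatments, Kit -0.06 between genotypes under vehicle and Trem2 0.13 between genotypes over both treatments. Thy1 between genotypes under vehicle and Thy1 between genotypes under PLX gained calls. Kdm5d and Mcm3 under PLX over both genotypes lost calls. Medians of lists that moved in call or direction were, over both genotypes, monocytes 0.52, neutrophils 0.77 and sex-linked -0.14. Called genes numbered 2 between genotypes over both treatments, 1 between genotypes under PLX and 1 between genotypes under vehicle.

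In the younger cohort alone, reversed in sign were Apoe 0.04 between genotypes over both treatments, Il34 -0.04 between genotypes under PLX, Mcm3 0.02 under PLX over both genotypes, P2ry12 -0.01 between genotypes under vehicle and Trem2 0.11 between genotypes over both treatments. Csf1 and Mbp under PLX over both genotypes and Bcas1, Csf1, Gng13, Il34, Kif5a, Kit, Mbp, Mobp, Omp, Rgs8, Rph3a, S100a5 and Thy1 in Ntg under PLX and Csf1, Il34, Omp, S100a5 and Serpina3n in a-syn-tg under PLX lost calls. Lists whose call or direction moved had medians over both genotypes of T and NK cells 0.72, cell cycle 2.34, disease-associated microglia -0.17, erythroid -1.55, monocytes 0.24, neurons 0.70, neutrophils 0.27, oligodendrocytes -0.42, p53 and apoptosis -0.14 and gene list: sex-linked -11.82. Called genes numbered 2826 in Ntg under PLX. With age cohort alone, reversed in sign were Csf1 0.13 in the interaction, Il34 -0.01 between genotypes under PLX, P2ry12 -0.06 between genotypes under vehicle, Snca -0.10 between genotypes under PLX, Thy1 -0.10 in the interaction and Tmem119 -0.01 between genotypes under vehicle. Snca in a-syn-tg under PLX and Thy1 between genotypes under vehicle and Thy1 between genotypes under PLX gained calls. Kdm5d and Mcm3 under PLX over both genotypes lost calls. Over both genotypes, lists whose call or direction moved had medians of monocytes 0.40, neutrophils 0.62 and gene list: sex-linked -3.87. Called genes numbered 2 between genotypes under PLX and 1 between genotypes under vehicle.

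With the compared groups alone, reversed in sign was Kit 0.00 between genotypes under vehicle. Snca in Ntg under PLX and Thy1 between genotypes under vehicle gained calls. Called genes numbered 1 between genotypes under vehicle. With the stricter filter, reversed in sign was Kit -0.01 between genotypes under vehicle. Lists whose call or direction moved had medians over both genotypes of lipid handling and efflux 0.12, neurons 1.01, neutrophils 0.76, p53 and apoptosis -0.35 and sex-linked -0.33.

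After thinning, reversed in sign was Kit -0.05 between genotypes under vehicle. Over both genotypes, lists whose call or direction moved had medians of monocytes 0.54, neutrophils 0.72 and sex-linked -0.41. Without the filter, reversed in sign was Thy1 -0.01 in the interaction. Thy1 between genotypes under PLX gained a call. Snca and Stmn1 under PLX over both genotypes and Bcas1, Kif5a and Mobp in Ntg under PLX lost calls. Medians of lists that moved in call or direction were, over both genotypes, B cells 0.40, cell cycle 0.98, lipid handling and efflux 0.03, sex-linked -0.38 and unfolded protein and integrated stress response -0.44. Called genes numbered 3 between genotypes over both treatments, 15 between genotypes under PLX and 6 in the interaction.

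Without Ntg PLX animal m490 and a-syn-tg PLX animal m488 together, Snca in a-syn-tg under PLX gained a call. Kdm5d under PLX over both genotypes lost a call. Lists whose call or direction moved had medians over both genotypes of monocytes 0.39, neutrophils 0.75, sex-linked -0.65 and synuclein and parkinsonism genes -0.04.

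Leaving out each animal gave these ranges. For genes with a reversal of sign: Apoe -0.01 to 0.07 under PLX over both genotypes, Apoe -0.02 to 0.03 between genotypes over both treatments, Kit -0.10 to 0.12 between genotypes under vehicle, P2ry12 -0.01 to 0.19 between genotypes under vehicle, Thy1 -0.28 to 0.39 in the interaction, Csf1 -0.29 to 0.01 in the interaction, Snca -0.19 to 0.34 between genotypes under PLX, Csf1 -0.07 to 0.16 between genotypes under PLX, Flt3 -0.18 to 0.24 in a-syn-tg under PLX, Il34 -0.04 to 0.12 between genotypes under PLX, Trem2 -0.21 to 0.08 between genotypes over both treatments and Flt3 -0.21 to 0.10 between genotypes under vehicle. For list medians over both genotypes: sex-linked -0.53 to -0.01, unfolded protein and integrated stress response -0.53 to -0.39, glycolysis and hypoxia 0.33 to 0.37, cell cycle 0.50 to 1.17, neutrophils 0.59 to 1.02, synuclein and parkinsonism genes -0.13 to -0.04 and monocytes 0.41 to 0.68. For called genes: 1 to 3 between genotypes over both treatments, 0 to 84 between genotypes under PLX, 0 to 1 between genotypes under vehicle and 0 to 4 in the interaction. Without Ntg PLX animal m467, Thy1 between genotypes under vehicle and Thy1 between genotypes under PLX gained calls. Without Ntg PLX animal m467, Snca under PLX over both genotypes lost a call. Without a-syn-tg PLX animal m468, Thy1 between genotypes under vehicle gained a call. Without a-syn-tg PLX animal m468, Kdm5d, Snca and Stmn1 under PLX over both genotypes lost calls. Without a-syn-tg PLX animal m481, Snca in a-syn-tg under PLX gained a call. Without a-syn-tg PLX animal m488, Thy1 between genotypes under PLX gained a call. Without a-syn-tg PLX animal m489, Snca in a-syn-tg under PLX and Thy1 between genotypes under vehicle and P2ry12, Thy1 and Tmem119 between genotypes under PLX gained calls. Without a-syn-tg vehicle animal m477, Kdm5d, Snca and Stmn1 under PLX over both genotypes and Thy1 in a-syn-tg under PLX lost calls. Without a-syn-tg vehicle animal m486, Snca in a-syn-tg under PLX gained a call. The monocyte call was lost without Ntg PLX animal m467 (0.41), without Ntg PLX animal m490 (0.43), without Ntg vehicle animal m476 (0.47), without Ntg vehicle animal m485 (0.45), without a-syn-tg PLX animal m468 (0.42), without a-syn-tg PLX animal m488 (0.52), without a-syn-tg PLX animal m489 (0.55), without a-syn-tg vehicle animal m484 (0.50) and without a-syn-tg vehicle animal m486 (0.46). The neutrophil call was lost without Ntg PLX animal m467 (0.69), without Ntg PLX animal m490 (0.76), without a-syn-tg PLX animal m468 (0.59), without a-syn-tg PLX animal m489 (0.88) and without a-syn-tg vehicle animal m486 (0.73).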

Other observations

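The terms for sex and age cohort held differences that were not among the planned comparisons, and all tests of them were chosen only after the result was seen. Male libraries differed from female ones in 27 genes, 6 higher and 21 lower. Lower in males were Eif2s3x (-0.66 ± 0.05 SE, adjusted p = 1.5e-05), Kdm6a (-0.77 ± 0.08, adjusted p = 5e-04) and Kdm5c (-0.68 ± 0.08, adjusted p = 0.00063). They are genes of the X chromosome that escape silencing and were chosen after their values were seen. Such genes were not tested as a group. Also lower in males were the receptor Tlr1 (-0.95 ± 0.12, adjusted p = 0.0038), the purine receptor P2ry13 (-0.86 ± 0.15, adjusted p = 0.047) and the chemokine Ccl12 (-1.23 ± 0.22, adjusted p = 0.047), also chosen after their values were seen. The homeostatic list had a median of -0.83 in males against females, with 24 members lower when adjusted over the list alone, and adjusted p = 0.29 with an estimated correlation. The cell cycle list had a median of -1.20, with 21 members lower when adjusted over the list alone, and adjusted p = 0.39 with an estimated correlation. Since the sex term equals a cohort by treatment interaction here, autosomal differences in it cannot be assigned to sex.

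Older against younger animals differed in 1 gene, Dmrtb1 (-1.91 ± 0.25, adjusted p = 0.034; chosen after its values were seen), with 2270 genes at an unadjusted p under 0.05 where 883 are expected. The homeostatic list had a median of -0.71 in the older cohort, with 23 members lower when adjusted over the list alone, and adjusted p = 0.43 with an estimated correlation. The cell cycle list had a median of -1.39, with 24 lower, and adjusted p = 0.51 with an estimated correlation. Vehicle cohorts overlapped, with homeostatic sums of 55820 to 70120 CPM in older and 54840 to 66450 CPM in younger animals. Cell cycle sums there were 385 to 399 and 351 to 469 CPM. PLX animals had homeostatic sums of 5537 to 11520 CPM (older) and 8942 to 21820 CPM (younger). Cell cycle sums under PLX were 300 to 342 and 348 to 2174 CPM. The age cohort term therefore does not show lower levels of these lists in older vehicle animals. Ttr (chromosome 18, 20665280 to 20674321, ENSMUSG00000061808), which carries thyroxine and retinol and was chosen after its values were seen, averaged 22760 CPM ± 4516 (SD, n = 4) in Ntg vehicle, 49830 CPM ± 10720 in Ntg PLX, 20810 CPM ± 6708 in a-syn-tg vehicle and 53950 CPM ± 8459 in a-syn-tg PLX. Its PLX effect over both genotypes was 1.32 ± 0.19 (adjusted p = 2.3e-05), and its sex (0.25 ± 0.19) and age cohort (-0.12 ± 0.19) terms did not pass.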
